A study of Gallus gallus with 38 samples.

How the data were processed

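Hepatocytes cultured from chicken embryos of day 19 had been exposed for 24 h to the solvent DMSO or to 1 of 7 treatments, per the labels. Each of the 38 arrays was hybridised with cRNA of 1 sample in Cy5 and, in Cy3, with a reference RNA made by pooling every control and treated sample in equal amounts. RNA had been isolated with RNeasy 96 kits with DNase treatment on the column, and 150 ng of total RNA per sample had been labelled with Quick Amp kits, per the labels' protocols.

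Feature Extraction (version 9.5.3.1 for 15 arrays and 9.5.1.1 for 23) wrote the mean pixel intensity of each spot and the median intensity of its local background in both dyes, not normalized, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 that this software computed after background subtraction, detrending and dye normalization, per the file headers. The deposited value table holds log2 ratios of sample over reference that the authors normalized by a method no header or label states. On the 4204 brightest probes, 36 of its 38 columns followed the loess-normalized ratios of their own array, computed as described below (r of at least 0.982). The columns of L-PFOS 10 uM replicates 2 and 3 followed no array (r with their own arrays 0.011 and 0.003), so the table served as an alternative only, without these 2 columns.

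From the intensities, background was corrected with limma's normexp method (offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with no scaling between arrays (limma 3.58.1 in R 4.3.3; python 3.11.15). Of 42034 probes for genes, the 32796 that were well above background in Cy5 on at least 4 arrays were tested; 131 of these lacked a spot on some array. Arrays had between 18515 and 35057 probes well above background (median 27664), and the number of arrays limits the precision.

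Gene names came from the files and from a table of RefSeq genes matched by accession, gene number, symbol or synonym, for 5842 probes; the other 36192 probes have no gene symbol, and 1473 of these carry a clone or locus name only. For a gene with several probes, the tested probe with the highest mean log2 intensity stood for the gene, which left 4890 genes. Positions are those in the files, on chicken build galGal 2. No genome was at hand, so exons and untranslated regions are not given.

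Group means were fitted to all 38 arrays with limma, and 13 comparisons were tested: each of the 7 treatments with DMSO, the 3 pairs of perfluorinated compounds at 10 uM, and the higher with the lower dose of L-PFOS, TCDD and PFUdA. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Changes are differences of mean log2 ratios, with limma's standard error (SE), and intervals are unadjusted 95% intervals. The genes named are, per comparison, up to 10 with the largest rises and 10 with the largest falls among those with a symbol that passed, the 5 with the smallest p where fewer than 5 passed, and up to 4 passing members of each list. Where compounds or doses are compared, genes named against DMSO are given too, and ALDH1A3, XDH and AKR1D1 are named beside the counts of their lists; these were chosen after their values were seen. In the comparisons with DMSO the genes CYP1A4, CYP1A5, TIPARP, CPT1A, FABP1, HMGCS1, CYP7A1, CYP3A37, CYP2H1 and THRSP were followed whatever their result; AHRR and CYP4B7, also chosen, are not on the array. CYP7A1 was not well above background in whole groups and is given no change. Some genes that this rule names are not reported here, but stand in the counts.

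Gene lists were fixed before the data were examined: targets of the aryl hydrocarbon receptor (AHR), of PPARA, of NRF2 and of p53; bile acid handling; cholesterol synthesis; lipogenesis; xenobiotic metabolism; thyroid hormone and IGF signalling; endoplasmic reticulum stress; heat shock; glycolysis and hypoxia; cell cycle; immune and interferon genes; hepatocyte plasma proteins; and markers of biliary, endothelial, erythroid, macrophage and fibroblast or stellate cells. Between 8 and 34 genes of each of the 20 lists were tested, and some genes stand in several lists. Each list was compared with all other genes by limma's camera test at a preset correlation of 0.01, over 260 pairs of list and comparison. Counts of members are given over all probes tested and, beside them, adjusted over the list alone. With the correlation estimated from the residuals, 12 of the 56 list results that passed still did: cholesterol synthesis for L-PFOS 40 uM and T-PFOS against DMSO and in both comparisons with L-PFOS 10 uM as the baseline (T-PFOS 10 uM, L-PFOS 40 uM), AHR targets in all 3 comparisons of TCDD, hepatocyte plasma proteins for both PFUdA doses against DMSO and for PFUdA against L-PFOS at 10 uM, NRF2 targets for PFUdA 10 uM, and erythroid markers for PFUdA against T-PFOS.

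The fit was tested on simulated data with the real number of arrays and 32796 probes. Over the 13 comparisons it recovered 76.1% to 91% of probes changed 1.5-fold, 88.1% to 98.5% of those changed 2-fold and 98.5% to 100% of those changed 4-fold, with 5 to 15 false calls. These simulations held no slide effects.

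The arrays lie on 10 slides with 3 to 4 groups each and were scanned on 7 days, 30 arrays on 1 scanner model and 8 on another. Comparisons were therefore also computed within slides and with slide as a block. Other alternatives were no background correction, median centring of each array in place of loess, scaling between arrays by Aquantile, the scanner log ratios, the value table, no filter and a filter at 19 arrays, the replicate number as a block, array weights, only the 2 groups compared, a threshold of 1.5-fold, genes in place of probes, and leaving out each array in turn. Alternatives chosen after the data were seen were the scanner model or the scan day as a block, the fit without the 8 arrays of the second scanner model, the value table without its 2 unmatched columns, and, for the gene lists, slide as a block. The second scanner model read DMSO replicates 2 and 5, TCDD 1 nM replicates 1 and 2 and PFUdA 1 uM replicates 2 and 3. It also read L-PFOS 40 uM replicate 3 and PFUdA 10 uM replicate 4, and no array of the other groups. Fits without these arrays therefore also rest on fewer arrays. Overlaps between comparisons with the same DMSO arrays were set against 50 simulated sets of unchanged groups and against splits of the DMSO arrays.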

Results

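Gene expression was measured on 38 two-colour arrays of cultured chicken embryonic hepatocytes after 24 h of exposure. Groups of 5 arrays held the solvent DMSO, linear perfluorooctane sulfonate (L-PFOS) at 10 uM and at 40 uM, technical-grade PFOS (T-PFOS, a mixture that holds branched isomers beside the linear one) at 10 uM, the dioxin TCDD at 0.03 nM, and linear perfluoroundecanoic acid (PFUdA) at 10 uM. Groups of 4 arrays held TCDD at 1 nM and PFUdA at 1 uM. Between 18515 and 35057 probes per array were well above background. The labels do not state that replicates are independent cultures, so each p measures the spread between these samples. All values are log2 ratios of a sample to the pooled reference, and changes are differences of group means with their standard errors (SE). Ratios of dim probes are drawn towards 0 by the offset, so folds and intervals within 1.5-fold apply to this scale. Reference-pool ratios of array pairs correlated from -0.556 upward, and 28 of 703 pairs lay under -0.3. None of these pairs was within a group, although negative values also occurred there.

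The response to 0.03 nM TCDD, a ligand of the aryl hydrocarbon receptor (AHR), was read from 5 exposed and 5 DMSO arrays. CYP1A4, an avian P450 enzyme induced through AHR (chromosome 10, 20160 to 20219), rose from -4.46 ± 0.125 (SD, n = 5) to 1.35 ± 0.279 (SD, n = 5). That is a change of 5.81 (SE 0.137, adjusted p = 8.4e-26), or 56.1-fold. CYP1A5, its paralog (chromosome 10, 15048 to 15107), rose by 2.94 (SE 0.168, adjusted p = 3.2e-14), and a probe named CYP1A2 rose by 2.65 (SE 0.176, adjusted p = 1.7e-12). TIPARP, an ADP-ribosyltransferase induced by AHR (chromosome 9, 22298671 to 22298730), rose by 1.87 (SE 0.089, adjusted p = 2.5e-16). Within the 2 slides that hold both groups, CYP1A4 changed by 5.50 to 5.97 and TIPARP by 1.67 to 1.81.

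Beyond these P450 genes, 0.03 nM TCDD was followed by a rise of RGN, the calcium-binding protein regucalcin, by 2.60 (SE 0.149, adjusted p = 3.2e-14) and of the transglutaminase gene TGM2 by 1.72 (SE 0.134). The protease gene MMP7 rose by 1.64 (SE 0.171) and MGP, an inhibitor of calcification, by 1.12 (SE 0.198; a second probe changed by 0.18 and did not pass). IAPP, which encodes islet amyloid polypeptide, fell by 1.93 (SE 0.289, adjusted p = 1.1e-04), FGF19, a hormone of bile acid feedback, by 1.18 (SE 0.145), and the acute-phase gene ORM1 by 0.80 (SE 0.123). KLHDC8B, FRZB and MYH15 fell too, by 1.23 (SE 0.14), 0.99 (SE 0.165) and 0.80 (SE 0.141). Of the 10 measured AHR targets 5 rose, the fifth being ALDH1A3 at 0.53, and the rest did not pass; adjusted over the list alone, 5 rose and 1 fell. The list's mean change was 1.32 and its median 0.35 (adjusted p = 2.6e-22, and adjusted p = 3.3e-09 with an estimated correlation), with means of 1.08 to 1.42 within slides. Of 17 p53 and apoptosis genes 2 rose, among them the cell cycle inhibitor CDKN1A by 0.76 (SE 0.142), and 2 rose adjusted over the list alone. Their mean change was 0.18, but -0.17 with median centring (adjusted p = 0.00222, and adjusted p = 0.0772 with an estimated correlation, with 0.02 to 0.22 within slides). Of 10 biliary markers MMP7 alone rose, also adjusted over the list alone, and the mean of 0.24 turned to -0.24 with median centring (adjusted p = 0.0388, adjusted p = 0.13 with an estimated correlation, and adjusted p = 0.0688 with slide as a block, with 0.09 to 0.26 within slides). CPT1A changed by 0.04 and did not pass. In all 218 probes passed, 125 higher and 93 lower, and 326 did so with slide as a block, 121 without the 8 arrays of the second scanner model (18 of 23 named calls left) and 126 in a fit of only the 2 groups (20 left). Without TCDD 0.03 nM replicate 3 the number was 135, and with median centring it was 36, with 12 of the 23 named calls left, those of CYP1A4, CYP1A5, CYP1A2, TIPARP, RGN, IAPP, FGF19, KLHDC8B and FRZB among them.

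The higher TCDD dose, 1 nM, was compared with DMSO on 4 and 5 arrays. CYP1A4 reached 2.55 ± 0.232 (SD, n = 4), a change of 7.01 (SE 0.145, adjusted p = 1.3e-27), or 129-fold. CYP1A2 rose by 3.59 (SE 0.187), CYP1A5 by 3.46 (SE 0.179), RGN by 3.38 (SE 0.158) and TIPARP by 1.98 (SE 0.095). TGM2, MMP7 and MGP rose by 2.23 (SE 0.142), 1.85 (SE 0.181) and 1.77 (SE 0.21). A second probe of MGP rose by 0.33 and passed. AREG, which encodes an EGF receptor ligand, rose by 1.46 (SE 0.149, adjusted p = 2.9e-08). ALAS1, the first enzyme of haem synthesis, rose by 0.82 (SE 0.16, adjusted p = 0.00246), and the interferon regulatory factor gene IRF1 by 0.55 (SE 0.094, adjusted p = 4.3e-04). Among the falls were IAPP by 2.10 (SE 0.307), FGF19 by 1.82 (SE 0.154), KLHDC8B by 1.51 (SE 0.148), and CYP24A1, the vitamin D hydroxylase, by 1.24 (SE 0.221). ORM1 fell by 1.15 (SE 0.13), THRSP, a thyroid-responsive lipogenic gene, by 1.13 (SE 0.194), SERPINF1 by 1.01 (SE 0.08), CTHRC1 by 0.99 (SE 0.17), and LBFABP, the liver basic fatty acid binding protein gene, by 0.90 (SE 0.178). LBFABP is a different gene from FABP1.

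At 1 nM TCDD 5 of 10 AHR targets rose and 1 fell, which was XDH at -0.57, and the counts were the same adjusted over the list alone. The list's mean was 1.59 and its median 0.45 (adjusted p = 1.1e-15, and adjusted p = 1.0e-07 with an estimated correlation; up to 1.79 within slides). Of 17 p53 and apoptosis genes CDKN1A rose, by 0.87 (SE 0.15), and was the 1 call adjusted over the list alone. The mean of these genes was 0.17 (adjusted p = 0.0388, and adjusted p = 0.221 with an estimated correlation, with 0.16 to 0.28 within slides), and it did not pass without the 8 arrays of the second scanner model (adjusted p = 0.346). Of 21 genes of thyroid hormone and IGF signalling 1 rose and 3 fell, THRSP among them, with the same counts adjusted over the list alone. Their mean was -0.16 (adjusted p = 0.0413, and adjusted p = 0.1 with an estimated correlation, with -0.25 to -0.10 within slides), and without those 8 arrays the adjusted p was 0.139. Neither list passed with median centring (adjusted p = 0.102 for p53 and 0.137 for thyroid hormone). In all 469 probes passed, 288 higher and 181 lower, and 890 did so with slide as a block, 225 without the 8 arrays of the second scanner model (16 of 32 named calls left) and 242 in a fit of only the 2 groups (22 left). With median centring the number was 70 and 13 of 32 named calls were left, those of RGN, TGM2, MMP7, MGP, AREG, IAPP, FGF19 and KLHDC8B among them.

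Whether the response to TCDD grew with dose was tested directly, 1 nM against 0.03 nM. CYP1A4 was higher at 1 nM by 1.20 (SE 0.145, adjusted p = 5.3e-05; 95% interval 0.90 to 1.49) and by 1.32 on the 1 slide with both groups. The other 3 probes that passed have no gene symbol. CYP1A2 differed by 0.94 (0.56 to 1.32, adjusted p = 0.0587), RGN by 0.79 (SE 0.158, adjusted p = 0.0607), GGT2 by 0.46 and TMTC1 by 0.41, none of which passed. CYP1A5 differed by 0.51 (0.15 to 0.88) and TIPARP by 0.11 (-0.08 to 0.30), which lies within 1.5-fold. Of 121 genes called at either dose all had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 1, and for 33 the interval reached beyond 1.5-fold without passing. As a list, AHR targets were higher at 1 nM with a mean of 0.27 (adjusted p = 0.00681, and adjusted p = 0.038 with an estimated correlation; 0.38 within the slide); CYP1A4 alone rose, and 3 rose and 1 fell adjusted over the list alone. With median centring limma called 0 probes (1885 at an unadjusted p under 0.05), and in a fit of only the 2 groups also 0 (1403). Leaving out TCDD 0.03 nM replicate 1 or 2 or TCDD 1 nM replicate 1 left 2 probes, leaving out TCDD 1 nM replicate 4 gave 10, and 2 were left without the 8 arrays of the second scanner model.

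**Figure D1:**
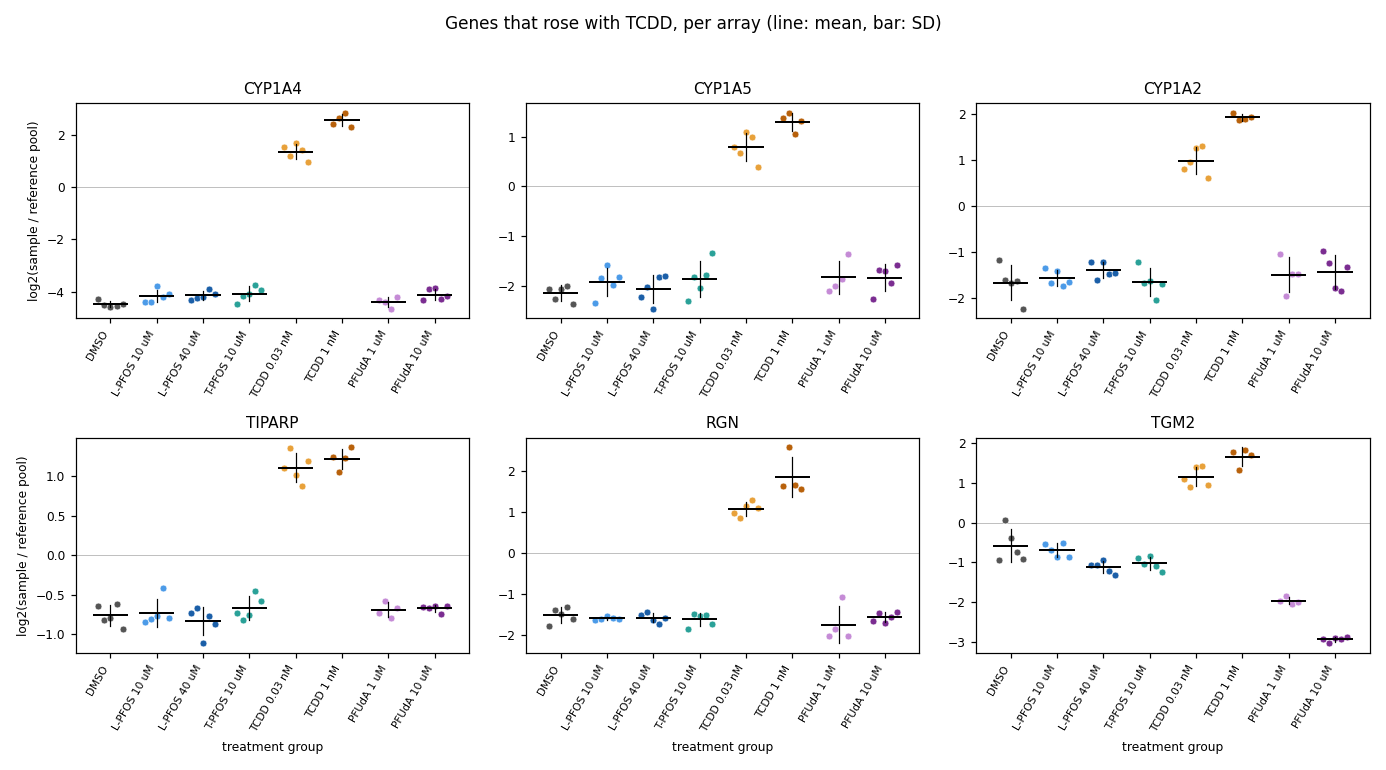
Log2 ratio to the reference pool (y axis) of 6 genes in each of the 8 groups (x axis); each point is 1 array, the line is the group mean and the bar its SD. CYP1A4 lies between 0.97 and 1.68 on the TCDD 0.03 nM arrays and between 2.31 and 2.83 on the TCDD 1 nM arrays, against a DMSO mean of -4.46.

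What linear PFOS does at 10 uM was asked on 5 exposed and 5 DMSO arrays. GSTA3, an alpha-class glutathione transferase gene (chromosome 3, 86694056 to 86694115), fell from 1.07 ± 0.389 (SD, n = 5) to -1.10 ± 0.192 (SD, n = 5), a change of -2.17 (SE 0.242, adjusted p = 9.7e-07). This probe, used for GSTA3 throughout, is named GSTA1 in the files. A second one, named GSTA3 there, changed by -1.15 and passed. MYH15, a myosin heavy chain gene (chromosome 1, 81505397 to 81505456), rose by 1.72 (SE 0.141, adjusted p = 1.5e-09), and GUCA2B, which encodes uroguanylin (chromosome 21, 5564209 to 5564269), by 1.12 (SE 0.11, adjusted p = 8.5e-08). The array annotation names the probe used for MYH15 throughout MYH6. On the 2 slides that hold both groups GSTA3 changed by -2.77 to -1.43 and MYH15 by 1.55 to 1.89. EDN2, an endothelin gene, rose by 1.11 (SE 0.152), INHBA, an activin subunit gene, by 0.86 (SE 0.136), ARHGEF4 by 0.89 (SE 0.141), TPPP by 0.74 (SE 0.137) and BMPER by 0.72 (SE 0.132). METTL7A fell by 1.18 (SE 0.118), and HSD3B7, an enzyme of bile acid synthesis, fell by 1.16 (SE 0.155). APOA4, an apolipoprotein gene, fell by 1.12 (SE 0.195), the defensin gene AvBD9 by 0.99 (SE 0.148), the surfactant protein gene SFTPA1 by 0.93 (SE 0.128) and the carbonic anhydrase gene CA4 by 0.89 (SE 0.177).

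No call was made at 10 uM L-PFOS for CYP1A4 (0.30, adjusted p = 0.395), CYP1A5 (adjusted p = 0.674) or TIPARP (0.03), nor for the fatty acid oxidation gene CPT1A (0.06). FABP1 changed by -0.73 (adjusted p = 0.153) and HMGCS1 by 0.24 (adjusted p = 0.53). Of 20 genes of xenobiotic metabolism GSTA3 and SULT1E1 fell and the rest did not pass; 4 fell adjusted over the list alone. The call of SULT1E1 ended without any 1 of 6 of the 10 arrays (adjusted p = 0.149 without DMSO replicate 3). Of the 26 named calls at this dose, 11 ended without some single array. The list's mean was -0.20 (adjusted p = 0.00455, but adjusted p = 0.405 with an estimated correlation and adjusted p = 0.452 with slide as a block), and it ranged from -0.44 to 0.11 within slides. For 10 biliary markers limma called 0 members (5 higher at an unadjusted p under 0.05), and 2 rose adjusted over the list alone. Their mean was 0.24, and -0.09 with median centring (adjusted p = 0.0326, adjusted p = 0.119 with an estimated correlation, adjusted p = 0.0607 with slide as a block, with 0.08 to 0.38 within slides). For 8 cholesterol synthesis genes it also called 0 (4 higher at an unadjusted p under 0.05; 1 rose adjusted over the list alone). Their mean was 0.17, and -0.14 with median centring (adjusted p = 0.045, but adjusted p = 0.234 with an estimated correlation, with 0.19 to 0.26 within slides). The AHR list had a mean of -0.17 and a median of 0.05 (adjusted p = 0.481); GSTA3 is the member that fell. In all 222 probes passed, 120 higher and 102 lower. The number was 1361 with slide as a block, 102 without DMSO replicate 3, 135 without L-PFOS 10 uM replicate 1, 125 without its replicate 3, 134 without the 8 arrays of the second scanner model (19 of 26 named calls left) and 98 in a fit of only the 2 groups (20 left). With median centring 10 probes passed, and of 26 named calls those of GSTA3, HSD3B7 and METTL7A were left.

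L-PFOS at 40 uM was compared with DMSO on 5 and 5 arrays. MYH15 rose by 1.98 (SE 0.141, adjusted p = 2.1e-11), GUCA2B by 1.56 (SE 0.11, adjusted p = 2.1e-11) and EDN2 by 1.36 (SE 0.152). LBFABP (chromosome 23, 5026386 to 5026445) rose by 1.5 (SE 0.167, adjusted p = 5.1e-07; 1.29 to 1.42 within slides). RRM2, a ribonucleotide reductase subunit gene, rose by 1.20 (SE 0.209), FGFBP1 by 1.02 (SE 0.164), BMPER by 0.93 (SE 0.132) and IGFBP1, an IGF binding protein gene, by 0.90 (SE 0.139). ACSL1, an acyl-CoA synthetase gene, rose by 0.63 (SE 0.09) and the chemokine gene IL8L1 by 0.60 (SE 0.121). GSTA3 fell by 2.31 (SE 0.242, adjusted p = 1.8e-07; -2.85 to -2.77 within slides; 1.19 on its second probe), MGP by 1.51 (SE 0.198; 0.34 on its second probe, which passed), AvBD9 by 1.31 (SE 0.148), HSD3B7 by 1.09 (SE 0.155), and ALB, which encodes serum albumin (chromosome 4, 51384020 to 51385098), by 1.04 (SE 0.143, adjusted p = 2.1e-05). KLHDC8B fell by 1.04 (SE 0.14), COLEC12 by 0.98 (SE 0.164), METTL7A by 0.93 (SE 0.118), APOA4 by 0.92 (SE 0.195), FETUB, a fetuin gene, by 0.83 (SE 0.177), UGT1A6, a glucuronosyltransferase gene, by 0.80 (SE 0.14), and ABCC2, a canalicular transporter gene, by 0.67 (SE 0.102).

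Of 8 cholesterol synthesis genes 5 rose at 40 uM L-PFOS, and 6 adjusted over the list alone. LSS, lanosterol synthase, rose by 0.56 (SE 0.103) and IDI1 by 0.55 (SE 0.115). The list's mean of 0.35 (adjusted p = 4.8e-06, and adjusted p = 0.0147 with an estimated correlation; 0.33 to 0.42 within slides) became -0.11 with median centring, which moved the median of all probes by -0.12. For 10 biliary markers limma called 0 members over all probes (5 higher at an unadjusted p under 0.05), 5 rose adjusted over the list alone, and the mean was 0.18 but -0.29 with median centring (adjusted p = 0.0165, adjusted p = 0.0772 with an estimated correlation, with 0.06 to 0.14 within slides). MGP was the 1 of 24 fibroblast and stellate markers that fell, 3 fell adjusted over the list alone, and the mean was -0.30 (adjusted p = 0.0092, but adjusted p = 0.356 with an estimated correlation, with -0.51 to -0.44 within slides). Of 20 xenobiotic genes GSTA3, ABCC2 and SULT1E1 fell, also adjusted over the list alone. Their mean was -0.21 (adjusted p = 0.0359, but adjusted p = 0.593 with an estimated correlation and adjusted p = 0.366 with slide as a block, with -0.33 to -0.29 within slides). CYP1A4 (0.33, adjusted p = 0.318), CYP1A5 (0.09), TIPARP (-0.07), and CPT1A (0.05) did not pass. In all 527 probes passed, 279 higher and 248 lower; 1624 did so with slide as a block, 338 without DMSO replicate 3, 290 without the 8 arrays of the second scanner model (30 of 43 named calls left) and 347 in a fit of only the 2 groups (34 left). With median centring 122 passed, of 43 named calls 12 were left (MYH15, EDN2, GSTA3, MGP, AvBD9, HSD3B7, ALB, KLHDC8B, COLEC12, METTL7A, APOA4 and IGFBP4), and 6 named genes changed sign, HYOU1 from 0.33 to -0.18 among them.

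T-PFOS was tested at 10 uM on 5 arrays against DMSO. MYH15 rose by 1.67 (SE 0.141, adjusted p = 2.2e-09; 1.92 to 2.09 within slides), LBFABP by 1.38 (SE 0.167, adjusted p = 3.5e-06), GUCA2B by 1.32 (SE 0.11) and EDN2 by 1.22 (SE 0.152). FABP7, a fatty acid binding protein gene, rose by 1.09 (SE 0.207), AREG by 1.02 (SE 0.14), RRM2 by 0.98 (SE 0.209), BMPER by 0.93 (SE 0.132) and ACSL1 by 0.66 (SE 0.09). GSTA3 fell by 2.14 (SE 0.242, adjusted p = 8.9e-07; -2.31 to -1.66 within slides; 1.18 on its second probe), AvBD9 by 1.41 (SE 0.148), the alcohol dehydrogenase gene ADH1C by 1.16 (SE 0.196), HSD3B7 by 1.1 (SE 0.155), APOA4 by 1.09 (SE 0.195) and MGP by 1.09 (SE 0.198; 0.34 on its second probe, which passed). METTL7A fell by 1.02 (SE 0.118), ALB by 0.96 (SE 0.143), UGT1A6 by 0.75 and ABCC2 by 0.56 (SE 0.102). CYP1A4 changed by 0.40 (SE 0.137, adjusted p = 0.153) and THRSP by -0.67 (adjusted p = 0.0531), and TIPARP (0.09), CYP1A5 (0.29), CPT1A (0.05) and HMGCS1 (adjusted p = 0.142) did not pass either.

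Cholesterol synthesis genes rose with T-PFOS, 4 of 8, and 6 rose and 1 fell adjusted over the list alone. LSS rose by 0.67 (SE 0.103, adjusted p = 1.2e-04) and MSMO1, a sterol oxidase gene, by 0.61 (SE 0.108). The list's mean was 0.40 (adjusted p = 1.6e-06, and adjusted p = 0.012 with an estimated correlation; 0.28 to 0.50 within slides) and did not pass with median centring (mean 0.12, adjusted p = 0.168). Of 34 genes of hepatocyte plasma proteins 3 fell, ALB, APOA4 and FETUB, and 5 fell adjusted over the list alone; FETUB did not pass without T-PFOS replicate 4 (adjusted p = 0.0507). Their mean was -0.22 (adjusted p = 0.00491, but adjusted p = 0.279 with an estimated correlation; -0.32 to -0.06 within slides). Of 20 xenobiotic genes GSTA3, ABCC2 and SULT1E1 fell, 6 fell adjusted over the list alone, and the mean was -0.26 (adjusted p = 0.00232, but adjusted p = 0.356 with an estimated correlation and adjusted p = 0.116 with slide as a block, with -0.23 to -0.14 within slides). In all 551 probes passed, 267 higher and 284 lower. The number was 973 with slide as a block, 337 without DMSO replicate 3, 361 without T-PFOS replicate 3 and 211 in a fit of only the 2 groups (24 of 35 named calls left). With median centring 43 passed, and of 35 named calls those of GSTA3, AvBD9, HSD3B7, METTL7A, MGP and EDN2 were left.

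**Figure D2:**
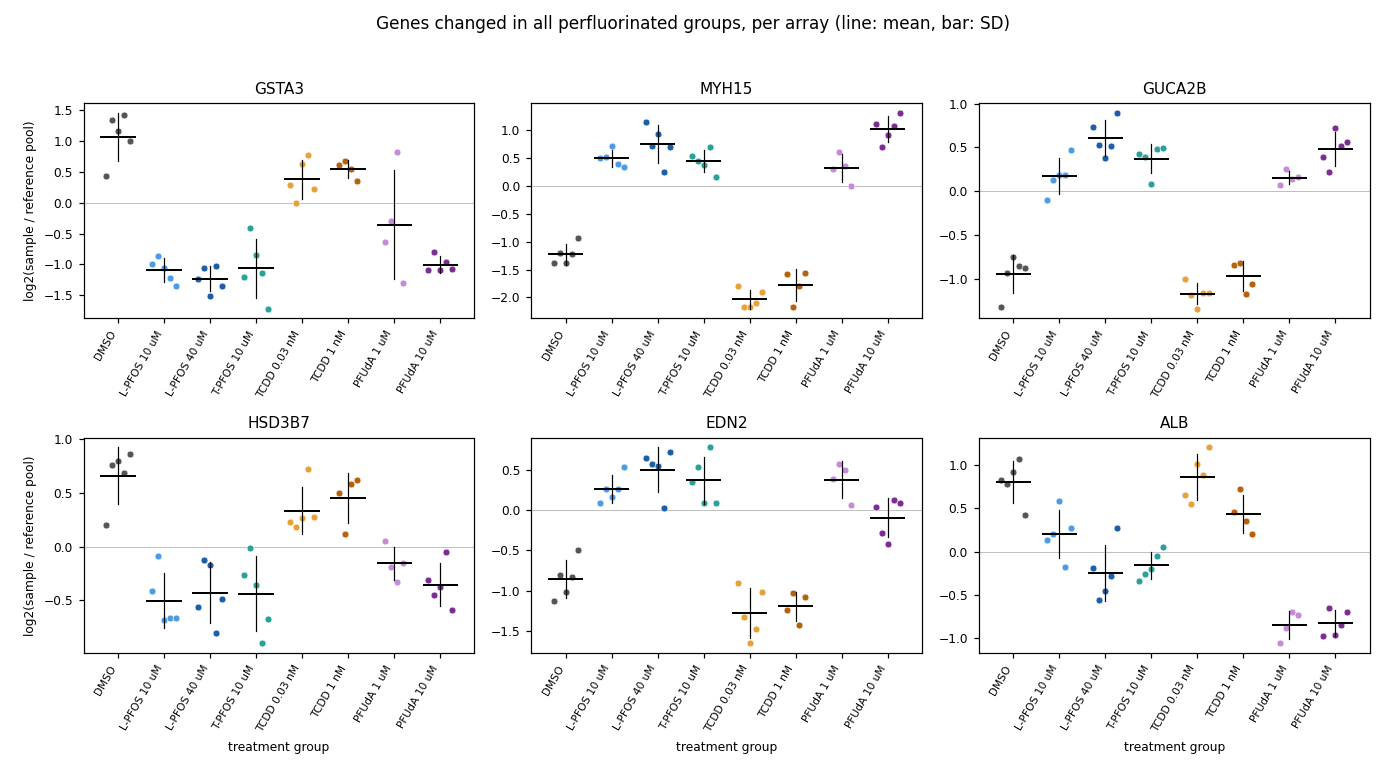
Log2 ratio to the reference pool (y axis) of 6 genes in each of the 8 groups (x axis); each point is 1 array, the line is the group mean and the bar its SD. GSTA3 has means of -1.10, -1.24 and -1.07 in L-PFOS 10 uM, L-PFOS 40 uM and T-PFOS 10 uM, against 1.07 in DMSO.

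Linear and technical-grade PFOS were compared at the same 10 uM, 5 arrays each, to ask where the isomer mixture acts differently. LBFABP was higher with T-PFOS by 0.95 (SE 0.167, adjusted p = 0.00676; 95% interval 0.61 to 1.29; 0.75 to 1.29 within 3 slides). SERPINF1, which encodes an antiangiogenic serpin, was lower by -0.56 (SE 0.075, adjusted p = 4.7e-04; -0.66 to -0.46 within slides), MUSTN1 by -0.69 (SE 0.11), the potassium channel subunit gene KCNMB1 by -0.54 (SE 0.094) and GLIPR2 by -0.36 (SE 0.062). GSTA3 differed by 0.03 (-0.46 to 0.52), MYH15 by -0.05 (-0.34 to 0.24), GUCA2B by 0.20 (-0.02 to 0.43), EDN2 by 0.11 (-0.20 to 0.42) and HSD3B7 by 0.06 (-0.25 to 0.38), and none of these passed. LSS (0.44, 0.23 to 0.65) did not pass either (adjusted p = 0.0897). Of 169 genes called with either compound 165 had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 6, for 128 the interval lay within 1.5-fold, and for 35 it reached beyond without passing. As a list, cholesterol synthesis was higher with T-PFOS, with a mean of 0.23 (adjusted p = 9.1e-05, and adjusted p = 0.0265 with an estimated correlation; 0.20 to 0.26 within slides); limma called 0 of its 8 genes (5 higher at an unadjusted p under 0.05), and 3 rose adjusted over the list alone. Hepatocyte plasma proteins had a mean of -0.18 (adjusted p = 0.0326, but adjusted p = 0.419 with an estimated correlation and 0.137 with median centring, with -0.30 to -0.22 within slides); 0 of 34 passed (8 lower and 1 higher at an unadjusted p under 0.05), and 6 fell adjusted over the list alone. In all 29 probes passed, 19 higher and 10 lower. The number was 180 with slide as a block, 19 without L-PFOS 10 uM replicate 1 and 13 without its replicate 3. With median centring limma called 0 (584 at an unadjusted p under 0.05), and in a fit of only the 2 groups 0 (2268).

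The lower PFUdA dose, 1 uM, was compared with DMSO on 4 and 5 arrays. FETUB fell by 1.72 (SE 0.187, adjusted p = 3.2e-07; -2.12 to -1.72 within slides) and ALB by 1.65 (SE 0.152, adjusted p = 1.8e-08; -1.66 to -1.12 within slides). GSTA3 fell by 1.43 (SE 0.256, adjusted p = 0.00105; 1.11 on its second probe), with a spread between arrays of 0.89 (SD, n = 4) and changes of -1.63 to -0.17 within slides. MBL2, a mannose-binding lectin gene, fell by 1.41 (SE 0.27), TGM2 by 1.38 (SE 0.142), PSPH, which makes serine, by 1.3 (SE 0.165), NELL2 by 1.13 (SE 0.207) and KLF1, an erythroid transcription factor gene, by 1.01 (SE 0.165). MYH15 rose by 1.55 (SE 0.149, adjusted p = 4.2e-08), INHBA by 1.28 (SE 0.145), EDN2 by 1.23 (SE 0.162), GUCA2B by 1.1 (SE 0.116), and FABP7 by 1.09 (SE 0.22). The thrombospondin gene THBS1 rose by 0.97 (SE 0.211), the follistatin gene FST by 0.94 (SE 0.18), PDGFB by 0.90 (SE 0.132) and IGF1 by 0.54 (SE 0.09). CYP1A4 (0.08), CYP1A5 (0.32), and TIPARP (0.07) did not pass.

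Of 34 hepatocyte plasma protein genes 10 fell at 1 uM PFUdA and 24 did not pass; 18 fell adjusted over the list alone. SPIA1, a serpin gene, was among them with -1.08 (SE 0.188). The mean was -0.49 and the median -0.43 (adjusted p = 1.4e-11, and adjusted p = 0.021 with an estimated correlation; -0.58 to -0.23 within slides). Of 17 PPARA targets 5 fell, with FABP1, the liver fatty acid binding protein gene, at -1.16 (SE 0.237), and 6 fell adjusted over the list alone. The mean was -0.26 (adjusted p = 0.00959, but adjusted p = 0.155 with an estimated correlation, with -0.20 to -0.13 within slides). Of 10 lipogenic genes THRSP (-1.17, SE 0.194) and ME1 fell, and 4 fell adjusted over the list alone; ME1 did not pass without PFUdA 1 uM replicate 3 (adjusted p = 0.0567). Their mean was -0.27 (adjusted p = 0.0223, but adjusted p = 0.164 with an estimated correlation and 0.171 with median centring, with -0.26 to -0.21 within slides). Of 20 xenobiotic genes 5 fell, with CYP2H2 at -0.62 (SE 0.132), and 1 rose and 6 fell adjusted over the list alone. The mean was -0.25 (adjusted p = 0.00816, but adjusted p = 0.447 with an estimated correlation; -0.29 to 0.15 within slides). Of 10 biliary markers 3 rose, with MMP7 at 0.86 (SE 0.181) and the trefoil gene TFF2 at 0.65 (SE 0.13), also adjusted over the list alone. The mean was 0.27 (adjusted p = 0.0104, but adjusted p = 0.0589 with an estimated correlation and 0.107 with median centring, with 0.25 to 0.45 within slides). For 26 cell cycle genes limma called 0 (5 higher at an unadjusted p under 0.05), 1 rose adjusted over the list alone, and the mean was 0.13 (adjusted p = 0.0217, but adjusted p = 0.279 with an estimated correlation, 0.137 with median centring and 0.219 without the second scanner model, with 0.22 to 0.25 within slides). In all 680 probes passed, 280 higher and 400 lower. The number was 1291 with slide as a block, 453 without DMSO replicate 2, 408 without PFUdA 1 uM replicate 3, 106 without the second scanner model (15 of 41 named calls left) and 292 in a fit of only the 2 groups (30 left). Leaving out that scanner model removed PFUdA 1 uM replicates 2 and 3 and DMSO replicates 2 and 5, so fewer arrays alone can lower the count. With median centring 40 passed, and of 41 named calls those of ALB, FETUB, NELL2, EDN2 and IGF1 were left.

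The higher PFUdA dose, 10 uM, was compared with DMSO on 5 arrays each. IFI6, an interferon-induced gene (chromosome 2, 89610413 to 89610472), rose by 3.24 (SE 0.221, adjusted p = 8.6e-13), or 9.44-fold, to 2.58 ± 0.202 (SD, n = 5), and by 2.73 to 3.23 within slides. LBFABP rose by 2.77 (SE 0.167, adjusted p = 6.4e-14; 2.59 to 3.22 within slides). CYP8B1, a sterol hydroxylase of bile acid synthesis (chromosome 2, 1638189 to 1638248), rose by 2.39 (SE 0.135, adjusted p = 1.5e-14), and SLC51B, a subunit of a bile acid exporter, by 2.32 (SE 0.174). KLF1 (chromosome 8, 20702243 to 20702302) fell by 2.74 (SE 0.156, adjusted p = 1.5e-14; -2.72 to -2.29 within slides), SPINK5, a protease inhibitor gene, by 2.52 (SE 0.17), the beta-defensin gene DEFB4A by 2.39 (SE 0.253) and TGM2 by 2.34 (SE 0.134). MYH15 rose by 2.25 (SE 0.141), MMP7 by 1.82 (SE 0.171), GATM, an enzyme of creatine synthesis, by 1.70 (SE 0.207), RRM2 by 1.56 (SE 0.209), HSD17B7 (chromosome 8, 3732247 to 3732306) by 1.31 (SE 0.103) and IGFBP1 by 1.22 (SE 0.139). GSTA3 fell by 2.08 (SE 0.242; 1.65 on its second probe), PSPH by 2.03 (SE 0.156), MBL2 by 1.87 (SE 0.254), PIT54, a haemoglobin-binding plasma protein gene of birds, by 1.70 (SE 0.186), ALB by 1.63 (SE 0.143), ORM1 by 1.58 (SE 0.123) and the metallothionein gene MT4 by 1.43 (SE 0.186). EPHX2 rose by 1.71 and GHR fell by 0.71, but a further probe of each had the opposite sign. CYP1A4 (0.36, adjusted p = 0.127), CYP1A5 (0.31), TIPARP (0.09), CPT1A (0.02) and FABP1 (-0.53, adjusted p = 0.192) did not pass.

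Of 34 hepatocyte plasma protein genes 18 fell at 10 uM PFUdA, also adjusted over the list alone, and 16 did not pass. Transferrin (TF) fell by 1.32 (SE 0.251), the fibrinogen chain gene FGB by 1.20 (SE 0.179) and APOB by 0.84 (SE 0.117). The mean was -0.54 and the median -0.49 (adjusted p = 2.1e-12, and adjusted p = 0.0167 with an estimated correlation; -0.41 to -0.32 within slides). Markers of other cell types did not pass as lists beside it. The mean was -0.23 for 15 erythroid markers (1 rose and 3 fell, adjusted p = 0.0966), 0.14 for 11 macrophage markers (1 rose and 1 fell; 3 and 1 adjusted over the list alone; adjusted p = 0.457) and 0.11 for 10 biliary markers (2 rose; median -0.08, adjusted p = 0.716). It was 0.02 for 24 fibroblast and stellate markers (3 rose and 1 fell, adjusted p = 0.996). Of 11 endothelial markers CLDN5 rose by 1.02 and CDH5 fell by 1.27, also adjusted over the list alone (adjusted p = 0.76). Of 16 NRF2 targets 5 fell, with GSTA3, MT4 and ME1 (-0.90, SE 0.118) among them, and 6 fell adjusted over the list alone. The mean was -0.39 (adjusted p = 0.00206, and adjusted p = 0.0309 with an estimated correlation, with -0.30 to -0.27 within slides). Of 11 bile acid genes 4 rose, CYP8B1, SLC51B, FGF19 (0.91, SE 0.145) and AKR1D1 (0.58), and HSD3B7 fell by 1.01, with the same counts adjusted over the list alone. The list's mean was 0.47 and its median 0.0062 (adjusted p = 0.0236, but adjusted p = 0.202 with an estimated correlation; 0.55 to 0.62 within slides). Cholesterol synthesis genes rose in 4 of 8 cases, with HSD17B7, LSS (0.47, SE 0.103) and MSMO1 (0.45, SE 0.108) among them, and in 5 adjusted over the list alone. Their mean was 0.36 (adjusted p = 0.00851, but adjusted p = 0.13 with an estimated correlation and 0.337 with median centring, with 0.23 to 0.46 within slides).

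Several further lists moved at 10 uM PFUdA. Of 19 genes of endoplasmic reticulum stress 5 fell, with ERO1A at -0.88 (SE 0.136) and HSP90B1 at -0.51 (SE 0.118), and 7 fell adjusted over the list alone. The mean was -0.21 (adjusted p = 0.00345, but adjusted p = 0.133 with an estimated correlation, with -0.30 to -0.11 within slides). Of 24 glycolysis and hypoxia genes EPAS1 rose by 0.56 (SE 0.099) and 5 fell, with EGLN3, an oxygen-sensing hydroxylase gene, at -1.04 (SE 0.13); 1 rose and 6 fell adjusted over the list alone. The mean was -0.20 (adjusted p = 0.02, but adjusted p = 0.326 with an estimated correlation, with -0.16 to -0.14 within slides). Of 10 lipogenic genes THRSP (-1.20, SE 0.183), ME1 and APOB fell, also adjusted over the list alone. The mean was -0.35 (adjusted p = 0.00206, but adjusted p = 0.0575 with an estimated correlation, with -0.25 within slides). Of 20 xenobiotic genes CYP2D6 rose by 0.71 (SE 0.126) and 5 fell, with ABCC2 at -0.85 (SE 0.102) and CYP2H2 at -0.63 (SE 0.124); the counts were the same adjusted over the list alone. The mean was -0.24 (adjusted p = 0.00491, but adjusted p = 0.408 with an estimated correlation and adjusted p = 0.0903 with slide as a block; -0.10 to 0.02 within slides). Of 26 cell cycle genes RRM2 rose, 6 rose adjusted over the list alone, and the mean was 0.23 (adjusted p = 0.0341, but adjusted p = 0.321 with an estimated correlation, adjusted p = 0.0536 with slide as a block and 0.213 with median centring, with 0.14 to 0.19 within slides). Immune and interferon genes did not pass as a list (mean 0.21, adjusted p = 0.0709), although 7 of 29 rose, with IL8L1 at 0.79 (SE 0.121) and IL8L2 at 0.68 (SE 0.126), and 9 rose and 2 fell adjusted over the list alone. Heat shock genes did not pass either (3 of 13 rose, also adjusted over the list alone; mean 0.20, adjusted p = 0.0683). In all 2156 probes passed, 1198 higher and 958 lower; 2891 did so with slide as a block and 1328 without the 8 arrays of the second scanner model (60 of 70 named calls left). With median centring 594 passed, 453 of them higher, and 30 of 70 named calls were left. They include IFI6, LBFABP, CYP8B1, SLC51B, KLF1, SPINK5, TGM2, GSTA3, ALB and MYH15.

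**Figure D3:**
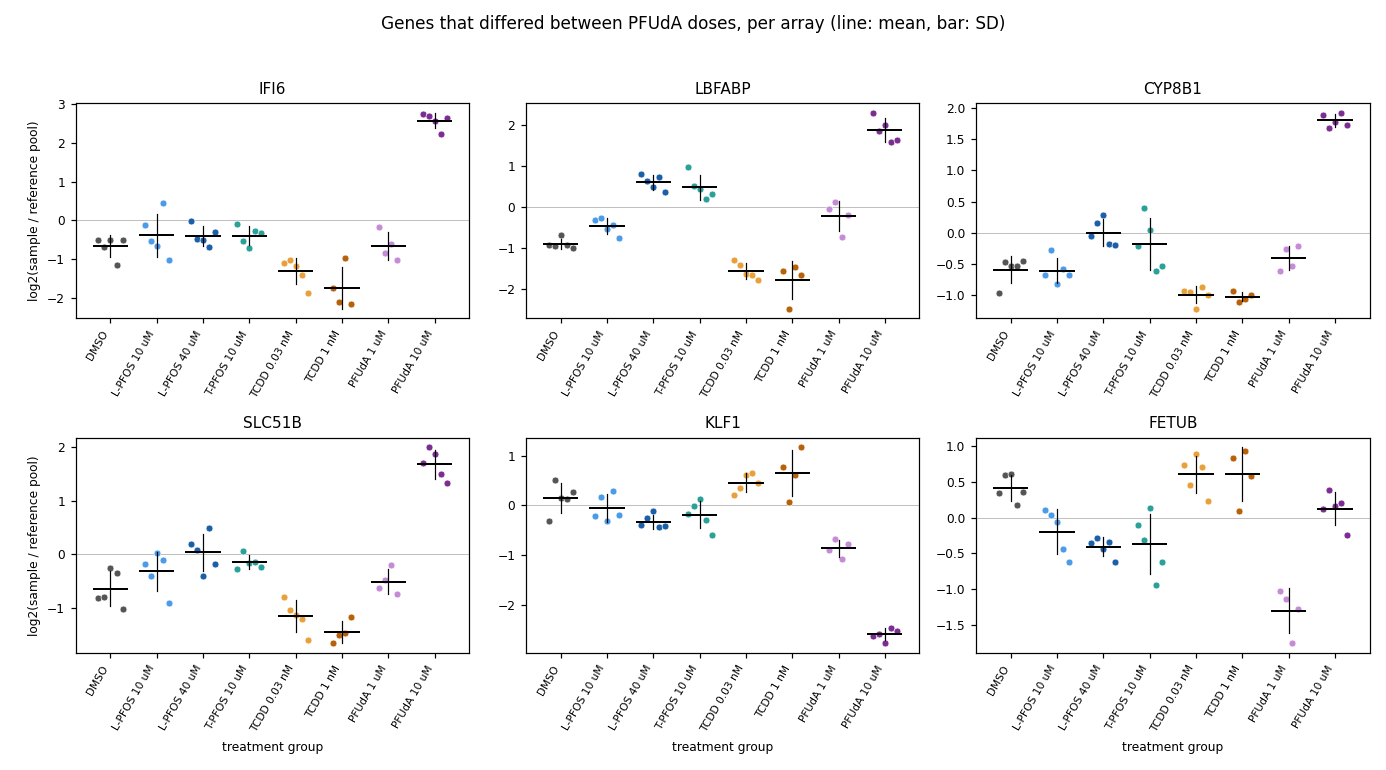
Log2 ratio to the reference pool (y axis) of 6 genes in each of the 8 groups (x axis); each point is 1 array, the line is the group mean and the bar its SD. IFI6 lies between 2.23 and 2.74 on the PFUdA 10 uM arrays, against a DMSO mean of -0.66, and FETUB has a mean of -1.3 at 1 uM PFUdA and 0.13 at 10 uM.

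How the carboxylic acid PFUdA differs from the sulfonate L-PFOS at 10 uM was tested on 5 arrays each. IFI6 was higher with PFUdA by 2.95 (SE 0.221, adjusted p = 9.8e-12; 95% interval 2.50 to 3.40; 2.13 to 3.36 within 4 slides), CYP8B1 by 2.41 (SE 0.135), LBFABP by 2.34 (SE 0.167), SLC51B by 1.99 (SE 0.174) and SCX, a tendon transcription factor gene, by 1.78 (SE 0.121). The difference was -2.77 (SE 0.17) for SPINK5, -2.54 (SE 0.156) for KLF1, -2.23 (SE 0.134) for TGM2 and -1.76 (adjusted p = 2.2e-08) for FGB. GSTA3 differed by 0.09 (-0.40 to 0.59) and HSD3B7 by 0.15 (-0.17 to 0.46) and did not pass, while MYH15 was higher by 0.53 (0.24 to 0.82, adjusted p = 0.0151), METTL7A higher by 1.25 (1.01 to 1.49) and ALB lower by -1.03 (-1.32 to -0.74). Of 519 genes called with either compound 381 had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 317. For 248, some of them among those that passed, the interval lay within 1.5-fold, and for 29 it reached beyond without passing. Of 34 hepatocyte plasma protein genes 18 were lower and 20 adjusted over the list alone, with a mean of -0.49 (adjusted p = 2.6e-10, and adjusted p = 0.0265 with an estimated correlation; -0.60 to -0.44 within slides). Of 11 bile acid genes 4 were higher and 1 lower, and 4 and 2 adjusted over the list alone (mean 0.48, median 0.05, adjusted p = 0.0165, but adjusted p = 0.172 with an estimated correlation, adjusted p = 0.0769 with slide as a block and 0.072 with median centring, with 0.28 to 0.49 within slides). Of 19 genes of endoplasmic reticulum stress 5 were lower, 6 adjusted over the list alone (mean -0.22, adjusted p = 0.00273, but adjusted p = 0.13 with an estimated correlation and 0.191 with median centring, with -0.32 to -0.03 within slides). Of 24 glycolysis genes 1 was higher and 6 lower, 1 and 10 adjusted over the list alone (mean -0.28, adjusted p = 0.00176, but adjusted p = 0.202 with an estimated correlation and 0.137 with median centring, with -0.41 to -0.15 within slides). Of 10 lipogenic genes 3 were lower, 4 adjusted over the list alone (mean -0.29, adjusted p = 0.0125, but adjusted p = 0.13 with an estimated correlation, with -0.39 to -0.27 within slides). Of 16 NRF2 targets 4 were lower, also adjusted over the list alone, with ME1 at -1.03 (mean -0.22, adjusted p = 0.045, but adjusted p = 0.164 with an estimated correlation, adjusted p = 0.0767 with slide as a block and 0.221 with median centring, with -0.27 to -0.20 within slides). In all 2022 probes passed, 1222 higher and 800 lower, 3681 with slide as a block and 571 with median centring, of which 513 were higher.

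Against T-PFOS at 10 uM, PFUdA gave 1551 probes, 894 higher and 657 lower. IFI6 was higher by 2.97 (SE 0.221, adjusted p = 1.2e-11; 2.84 to 3.42 within 3 slides), CYP8B1 by 1.98 (SE 0.135), SLC51B by 1.83 (SE 0.174), MMP7 by 1.73 (SE 0.171), LBFABP by 1.39 (SE 0.167), AvBD9 by 1.3 (SE 0.148) and FGF19 by 1.25 (SE 0.145). SPINK5 differed by -2.56 (SE 0.17), KLF1 by -2.40 (SE 0.156), TGM2 by -1.90 (SE 0.134), PIT54 by -1.56, CDH5, which encodes an endothelial cadherin, by -1.42 (SE 0.118) and ORM1 by -1.37. GSTA3 differed by 0.06 (-0.43 to 0.55) and GUCA2B by 0.11 (-0.11 to 0.33), which did not pass, and MYH15 was higher by 0.58 (0.30 to 0.87, adjusted p = 0.00828) and ALB lower by -0.67 (-0.96 to -0.38). Of 554 genes called with either compound 446 had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 270. For 284, some of them among those that passed, the interval lay within 1.5-fold, and for 62 it reached beyond without passing. Of 34 hepatocyte plasma protein genes 11 were lower, and 1 higher and 12 lower adjusted over the list alone (mean -0.31, adjusted p = 4.2e-08, but adjusted p = 0.052 with an estimated correlation, with -0.24 to -0.22 within slides). Of 15 erythroid markers KLF1 and CA2 were lower, also adjusted over the list alone (mean -0.27, median -0.06, adjusted p = 0.0038, and adjusted p = 0.021 with an estimated correlation; -0.28 to -0.24 within slides). CA2 did not pass without any 1 of 7 of the 10 arrays (adjusted p = 0.193 without T-PFOS replicate 1). Of 11 bile acid genes 4 were higher, and 4 higher and 1 lower adjusted over the list alone (mean 0.51, adjusted p = 0.00351, but adjusted p = 0.1 with an estimated correlation, with 0.52 to 0.62 within slides). Of 19 genes of endoplasmic reticulum stress 4 were lower, also adjusted over the list alone (mean -0.24, adjusted p = 9.1e-05, but adjusted p = 0.052 with an estimated correlation, with -0.38 to -0.05 within slides). Of 24 glycolysis genes 2 were higher and 7 lower, also adjusted over the list alone (mean -0.24, adjusted p = 2.7e-04, but adjusted p = 0.147 with an estimated correlation, with -0.27 to -0.09 within slides). Of 10 lipogenic genes 2 were lower, 3 adjusted over the list alone (mean -0.24, adjusted p = 0.00491, but adjusted p = 0.0951 with an estimated correlation, with -0.26 to -0.22 within slides). With slide as a block 2292 probes passed and with median centring 382, of which 333 were higher.

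For L-PFOS the 40 uM dose was compared with 10 uM on 5 arrays each. LBFABP was higher at 40 uM by 1.07 (SE 0.167, adjusted p = 0.00122; 1.01 to 1.13 within 2 slides). SERPINF1 was lower by -0.62 (SE 0.075, adjusted p = 6.4e-05; -0.97 to -0.47 within slides), KCNMB1 by -0.68 (SE 0.094, adjusted p = 3.0e-04) and TSPAN2, a tetraspanin gene, by -0.56 (SE 0.086, adjusted p = 0.00112). GSTA3 differed by -0.14 (95% interval -0.63 to 0.35), MYH15 by 0.26 (-0.03 to 0.54), GUCA2B by 0.44 (0.22 to 0.66, adjusted p = 0.127) and ALB by -0.44 (-0.74 to -0.15, adjusted p = 0.381), and none passed. The comparison of T-PFOS with L-PFOS at 10 uM has the same baseline arrays. It called LBFABP, SERPINF1, KCNMB1 and TSPAN2 the same way, and cholesterol synthesis passed as a list in both. Leaving out some single array ended 8 of the 12 named calls here. Of 170 genes called at either dose 163 had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 10, for 117 the interval lay within 1.5-fold, and for 43 it reached beyond without passing. Members of 4 lists that passed were each below the threshold over all probes, where limma called 0. Cholesterol synthesis genes were higher by a mean of 0.18 (4 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone; adjusted p = 3.8e-04, adjusted p = 0.0395 with an estimated correlation, adjusted p = 0.115 with median centring, with 0.02 to 0.14 within slides). Fibroblast and stellate markers had a mean of -0.27 (4 lower unadjusted, 1 adjusted over the list alone; adjusted p = 0.00681, but adjusted p = 0.326 with an estimated correlation), with -0.24 to 0.10 within slides. Cell cycle genes had a mean of -0.14 (4 lower and 1 higher unadjusted, 0 adjusted over the list alone; adjusted p = 0.0327, but adjusted p = 0.321 with an estimated correlation and adjusted p = 0.055 with slide as a block, with -0.17 to -0.13 within slides). PPARA targets had a mean of 0.05, but -0.09 with median centring (2 higher unadjusted, 0 adjusted over the list alone; adjusted p = 0.0412, but adjusted p = 0.239 with an estimated correlation and adjusted p = 0.101 with slide as a block, with -0.03 to 0.18 within slides). In all 42 probes passed, 21 each way, and 71 with slide as a block; without L-PFOS 10 uM replicates 1 to 4 the numbers were 16, 24, 12 and 23, and without L-PFOS 40 uM replicates 1 to 5 they were 25, 19, 19, 25 and 18. With median centring limma called 0 (525 at an unadjusted p under 0.05), a fit of only the 2 groups gave 7, and 16 passed without the 8 arrays of the second scanner model, with 5 of 12 named calls left in each of these 2.

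The PFUdA doses were compared on 5 arrays at 10 uM and 4 at 1 uM. IFI6 was higher at 10 uM by 3.24 (SE 0.234, adjusted p = 7.1e-12; 2.84 on the 1 slide with both groups), NELL2 by 2.24 (adjusted p = 1.8e-09), GATM by 2.22, CYP8B1 by 2.20 (adjusted p = 1.0e-12), and SLC51B by 2.19. LBFABP was higher by 2.08 (SE 0.178) and FETUB by 1.43 (SE 0.187, adjusted p = 2.2e-06). KLF1 was lower by -1.73 (adjusted p = 3.8e-09), SPINK5 by -1.69, INHBA by -1.14 (SE 0.145), EGLN3 by -1.14, PIT54 by -1.09 and CDH5 by -0.98. ALB differed by 0.02 (95% interval -0.29 to 0.33), which lies within 1.5-fold, GSTA3 by -0.65 (-1.17 to -0.13, adjusted p = 0.152), and MYH15 was higher by 0.70 (0.40 to 1.00, adjusted p = 0.0022). Of 578 genes called at either dose 435 had the same sign, which is favoured by the DMSO arrays that both changes share. The difference passed for 268. For 285, some of them among those that passed, the interval lay within 1.5-fold, and for 74 it reached beyond without passing. Of 29 immune and interferon genes 8 were higher and 1 lower, also adjusted over the list alone (mean 0.22, median 0.05, adjusted p = 0.0327, but adjusted p = 0.1 with an estimated correlation, 0.113 with slide as a block and 0.101 without the second scanner model, with 0.17 within the slide). Of 11 bile acid genes 4 were higher and 1 lower, also adjusted over the list alone (mean 0.48, adjusted p = 0.0254, but adjusted p = 0.202 with an estimated correlation, with 0.44 within the slide). HSD17B7 was the 1 of 8 cholesterol synthesis genes that was higher, by 1.22, also adjusted over the list alone (mean 0.29, adjusted p = 0.04, but adjusted p = 0.221 with an estimated correlation and 0.248 with median centring, with 0.35 within the slide). ERO1A was the 1 of 19 genes of endoplasmic reticulum stress that was lower, also adjusted over the list alone (mean -0.20, adjusted p = 0.0177, but adjusted p = 0.221 with an estimated correlation and 0.0767 with median centring, with -0.39 within the slide). Of 24 glycolysis genes 2 were higher and 2 lower, and 2 and 8 adjusted over the list alone (mean -0.21, adjusted p = 0.00605, but adjusted p = 0.254 with an estimated correlation, 0.0756 with median centring and 0.126 without the second scanner model, with -0.46 within the slide). Of 16 NRF2 targets 3 were lower, and 1 higher and 3 lower adjusted over the list alone (mean -0.17, adjusted p = 0.0403, but adjusted p = 0.155 with an estimated correlation, 0.156 with slide as a block, 0.164 with median centring and 0.13 without the second scanner model, with -0.31 within the slide). In all 1929 probes passed, 1250 higher and 679 lower. The number was 2922 with slide as a block, 665 without the second scanner model (38 of 60 named calls left) and 454 with median centring, of which 419 were higher.

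**Figure D4:**
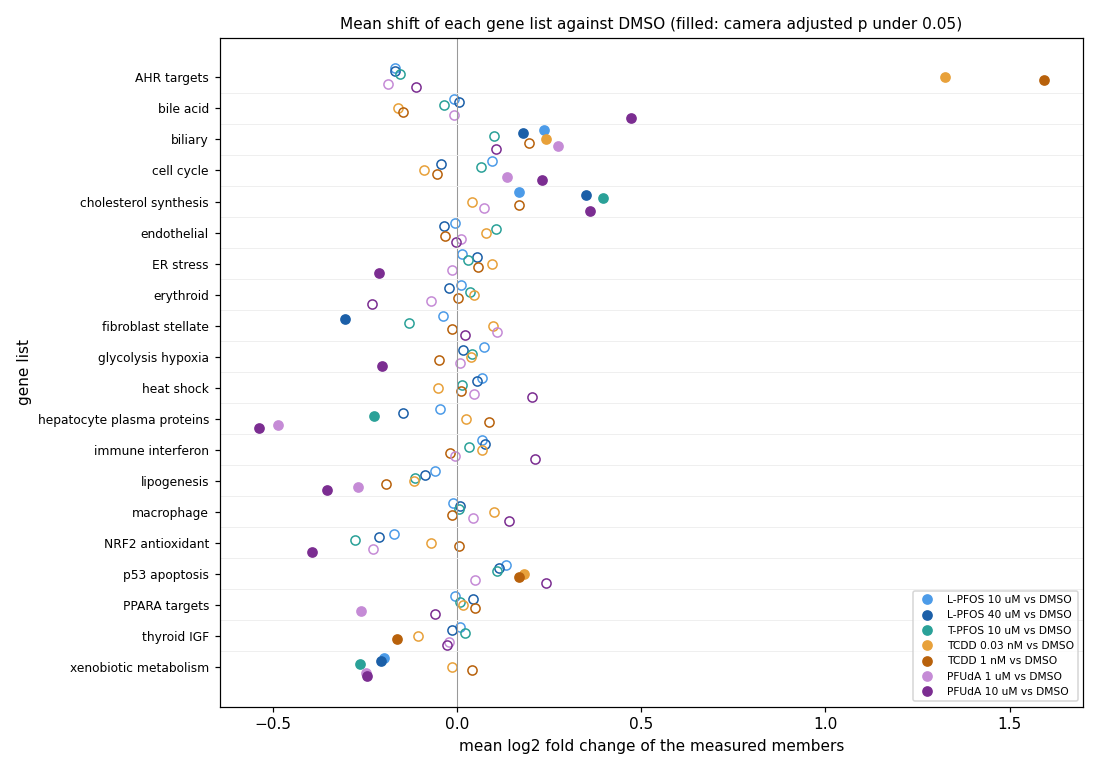
Mean log2 change against DMSO (x axis) of each of the 20 gene lists (y axis) in the 7 treatments; filled points passed the camera test and open points did not. AHR targets stand at 1.32 and 1.59 in the TCDD groups, and hepatocyte plasma proteins at -0.49 and -0.54 in the PFUdA groups; for biliary, cholesterol and p53 genes with L-PFOS or 0.03 nM TCDD the sign turns with median centring.

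Genes shared between comparisons with DMSO were counted to ask how alike the responses are. The same DMSO arrays serve each comparison, and simulated unchanged groups gave 0 shared probes each way in all 21 pairs (limma). The threshold alone holds that count near 0, so covariances and counts with split DMSO arrays are given beside. Neither allows for slides: arrays of different groups on the same slide deviate together (mean residual correlation 0.338). L-PFOS, T-PFOS and PFUdA at 10 uM, among others, have slides in common, so part of an overlap, or of a covariance above the simulated value, can come from shared slides. L-PFOS and T-PFOS at 10 uM shared 71 probes higher and 66 lower, where independent lists would share 0.98 and 0.88; with DMSO arrays split between them the median was 34 in the same direction. The covariance of their changes was 0.0165, against 0.007 in the simulation. T-PFOS and PFUdA at 10 uM shared 149 higher and 139 lower (independent lists 9.75 and 8.3; split 101.5) with 10 in opposite directions, and L-PFOS and PFUdA at 10 uM shared 66 and 55 (4.38 and 2.98; split 32.5) with 5 opposite. The covariances were 0.0228 and 0.0132, against 0.0073 and 0.0072 simulated. With PFUdA at 1 uM the covariance was 0.0137 for T-PFOS (0.0063 simulated) but 0.0087 for L-PFOS 10 uM and 0.0067 for L-PFOS 40 uM, against 0.0065 simulated for both. L-PFOS at its 2 doses shared 79 and 55 (1.02 and 0.77; split 35.5; covariance 0.0156 against 0.006), TCDD at its 2 doses 110 and 78 (1.1 and 0.51; split 73.5; 0.0146 against 0.0074), and PFUdA at its 2 doses 121 and 183 with 21 opposite (10.23 and 11.68; split 122; 0.0179 against 0.0067). TCDD 1 nM and PFUdA 10 uM shared 68 and 55 (10.52 and 5.29, split 48) and had 53 opposite, with a covariance of 0.0035 against 0.0072 simulated. L-PFOS 40 uM and TCDD 0.03 nM shared 12 and 23 (1.06 and 0.7, split 10) and had 17 opposite (0.003 against 0.007). Above the simulated covariance lay TCDD 0.03 nM with PFUdA 10 uM (0.0078 against 0.0067) and with T-PFOS (0.0082 against 0.0071). So did TCDD 1 nM with L-PFOS 10 uM (0.0103 against 0.0076) and 40 uM (0.0106 against 0.0061). The other pairs of TCDD with a perfluorinated group lay below it. In all 5 perfluorinated groups 59 probes changed the same way, 34 higher and 25 lower, and 57 of the 59 kept that direction when the 9 TCDD arrays stood in for DMSO. Among the 23 with a symbol, MYH15, GUCA2B, EDN2, PDGFB and TPPP were higher and GSTA3, HSD3B7, ALB, APOA4 and SFTPA1 lower. Of the 59, 19 were also called in a TCDD comparison, 11 of them the same way. SFTPA1 is such a gene: it fell by 0.63 at 0.03 nM TCDD (adjusted p = 0.00739) and by 0.67 at 1 nM (adjusted p = 0.00382).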

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

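The tests of the shared probes against the TCDD arrays, of the other cell types and of the correlation within slides were chosen only after the result was seen; the other tests were chosen before. Among 96 groups of arrays 6 held a sample far from the others by Dixon's test, where chance flags about 1 in 20 groups, or 4.8 here. TIPARP stood at -0.418 on L-PFOS 10 uM replicate 4, against -0.845 to -0.767 on the other 4 arrays. CYP2H1 stood at -0.449 on TCDD 0.03 nM replicate 2 (others -0.197 to -0.125). CYP7A1, which was not well above background there, stood at 0.114 on TCDD 0.03 nM replicate 4 (others -0.041 to -0.006) and at -0.024 on TCDD 1 nM replicate 3 (others 0.138 to 0.158). On L-PFOS 40 uM replicate 3, 18515 probes were well above background (others 26823 to 29318), and the median Cy5 signal of PFUdA 10 uM replicate 4 was 163.3 (others 84.3 to 94.2); both are arrays of the second scanner model.

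Each count of probes was set against 100 other splits of the same arrays. The real grouping gave the most probes in all 13 comparisons, which is rank 1 of 100. The highest other split was 4 for L-PFOS 10 uM, 19 for L-PFOS 40 uM, 422 for T-PFOS, 6 for TCDD 0.03 nM, 195 for TCDD 1 nM, 487 for PFUdA 1 uM and 661 for PFUdA 10 uM, each against DMSO. It was 1 for T-PFOS against L-PFOS, 263 and 236 for PFUdA against L-PFOS and T-PFOS, and 1, 2 and 939 for the doses of L-PFOS, TCDD and PFUdA.

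The 59 probes that changed the same way in all 5 perfluorinated groups, MYH15 and GSTA3 among them, could come from DMSO arrays that stand apart. Against the 9 TCDD arrays in place of DMSO their median change in the shared direction was 0.579, and 57 of the 59 kept it, against 0.7334 from DMSO. This argues against that explanation. They could also come from arrays of the second scanner model, but on the first scanner model alone the median was 0.7532 and all 59 kept their direction. The probes had been chosen on all 38 arrays, the 30 of the first model among them. They were therefore likely to keep their direction, and this check on the scanner model is weak. A response to the perfluorinated compounds stays open and is not shown by these tests.

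The fall of hepatocyte plasma protein genes at 10 uM PFUdA could reflect a lower share of hepatocytes among the cells. Markers of all other cell types would then move up together, but of 70 such markers 6 passed as lower, in 4 of the 5 cell types, and 8 as higher, where false calls would allow 2 lower. HBA1 (-0.44) and LYZ (-0.58) are among the lower ones, but a second probe of each did not pass (-0.005 and -0.07). LYZ is the only macrophage marker that passed as lower. CDH5 (-1.27, SE 0.118) and KLF1 (-2.74, SE 0.156) fell and CLDN5 (1.02, SE 0.124) and FAP (1.11, SE 0.19) rose, and all 4 kept their direction and passed with slide as a block, without the 8 arrays of the second scanner model and with median centring; 2 markers passed as lower in the last setting, 4 without the 8 arrays and 10 with slide as a block. The mean of all 70 was -0.0046 (SE 0.0661). As a set the markers thus did not move up. The rule on markers that passed as lower was written after the result was seen, so its outcome was not open. CDH5 and CLDN5, both endothelial markers, moved in opposite directions, so single markers need not follow the share of their cells. A lower share of hepatocytes is therefore not decided by this test. It was added after a test on the means of the 5 lists, whose bound was loosened after the erythroid mean (-0.23, SE 0.186) was seen. The gap of those means, 0.3731 (SE 0.2171), did not exceed 0.2 by more than its SE, which decided nothing. Arrays of the second scanner model do not account for the fall, since the mean on the first model was -0.5374, against -0.5371 on all arrays. Lower expression of these genes within hepatocytes stays open and was not tested.

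With slide as a block the count for L-PFOS 10 uM against DMSO went from 222 to 1361 probes. Residuals of arrays on the same slide correlated at 0.338 on average, and those on different slides at -0.031, so slides that shift together may account for the gain. The blocked fit could also call probes under any grouping, but the real grouping ranked 1 of 100 splits in that fit. The highest other split there gave 1276 and the median of the others was 0.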

How the results depend on the processing

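Among the 474 calls of named genes none changed direction except with median centring, which kept 147, ended 321 and reversed 6. The calls kept were 474 with Aquantile scaling, 465 without background correction, 448 with scanner log ratios, 422 with the value table, 459 without a filter, 454 with slide as a block, 461 with scanner model as a block, 352 without the 8 arrays of the second scanner model, 390 in fits of only the 2 groups, and 363 when each array was left out in turn. For the changes below the cause was not tested, apart from stricter thresholds and fits with fewer samples. Scanner model and scan day as blocks, the fit without the 8 arrays, the value table without 2 columns and slide as a block for lists were chosen after the data were seen. Signal limits the data too: the second scanner model gave 18515 to 27127 probes well above background per array, and the first 24418 to 35057.

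With median centring the numbers of probes were 10 for L-PFOS 10 uM, 122 for L-PFOS 40 uM, 43 for T-PFOS, 36 for TCDD 0.03 nM, 70 for TCDD 1 nM, 40 for PFUdA 1 uM and 594 for PFUdA 10 uM against DMSO. They were 0 for T-PFOS against L-PFOS, 571 and 382 for PFUdA against L-PFOS and T-PFOS, and 0, 0 and 454 for the doses of L-PFOS, TCDD and PFUdA. At an unadjusted p under 0.05 limma gave 584, 525 and 1885 probes where the count was 0. The share of probes that were higher went from 54.1% to 10% for L-PFOS 10 uM, from 52.9% to 14.8% for L-PFOS 40 uM, and from 64.8% to 92.3% for the PFUdA doses. List means that turned negative in this setting were those of cholesterol genes for L-PFOS 10 uM (-0.142), where the direction of the test turned too, and 40 uM (-0.111), biliary markers for L-PFOS 10 uM (-0.09) and 40 uM (-0.294) and TCDD 0.03 nM (-0.244), p53 genes for TCDD 0.03 nM (-0.17) and PPARA targets for the L-PFOS doses (-0.093). Named genes reversed for L-PFOS 40 uM were HSD17B7 (-0.071), HYOU1 (-0.184), SLC2A1 (-0.189), HSPA9 (-0.151), IRF1 (-0.092) and BTG2 (-0.084).

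With slide as a block the numbers were 1361 for L-PFOS 10 uM, 1624 for L-PFOS 40 uM, 973 for T-PFOS, 890 for TCDD 1 nM and 1291 for PFUdA 1 uM against DMSO, 180 for T-PFOS and 3681 for PFUdA against L-PFOS, 71 for the L-PFOS doses and 2922 for the PFUdA doses. With scan day as a block they were 570 for L-PFOS 10 uM, 1526 for L-PFOS 40 uM, 904 for TCDD 1 nM, 94 for T-PFOS and 3245 for PFUdA against L-PFOS, 78 for the L-PFOS doses and 7 for the TCDD doses. Without the 8 arrays they were 134 for L-PFOS 10 uM, 290 for L-PFOS 40 uM, 121 for TCDD 0.03 nM, 225 for TCDD 1 nM, 106 for PFUdA 1 uM, 1328 for PFUdA 10 uM, and 16, 2 and 665 for the doses of L-PFOS, TCDD and PFUdA. The value table without 2 columns gave 66 for L-PFOS 10 uM, 2 for T-PFOS against L-PFOS and 8 for the L-PFOS doses. Array weights gave 868 for L-PFOS 40 uM and 27 for the TCDD doses, and scanner log ratios gave 7 for the TCDD doses.

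Fits of only the 2 groups gave 98 for L-PFOS 10 uM, 347 for L-PFOS 40 uM, 211 for T-PFOS, 126 for TCDD 0.03 nM, 242 for TCDD 1 nM, 292 for PFUdA 1 uM, 0 for T-PFOS against L-PFOS (2268 at an unadjusted p under 0.05), 7 for the L-PFOS doses and 0 for the TCDD doses (1403). A fold change of at least 1.5 left 91, 194, 200, 112, 217, 301 and 672 for L-PFOS 10 and 40 uM, T-PFOS, TCDD 0.03 and 1 nM and PFUdA 1 and 10 uM against DMSO, 12 for T-PFOS and 613 for PFUdA against L-PFOS, 477 for PFUdA against T-PFOS, and 19, 2 and 639 for the doses. Genes with a symbol, 1 probe each, numbered 63, 151, 150, 62, 110, 185, 496, 8, 452, 361, 12, 1 and 410 in the same order.

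Leaving out 1 array at a time gave 102 to 233 for L-PFOS 10 uM, 338 to 500 for L-PFOS 40 uM, 337 to 607 for T-PFOS, 135 to 221 for TCDD 0.03 nM, 322 to 434 for TCDD 1 nM, 408 to 770 for PFUdA 1 uM and 1721 to 2400 for PFUdA 10 uM against DMSO. It gave 13 to 42 for T-PFOS and 1622 to 1908 for PFUdA against L-PFOS, 1249 to 1562 for PFUdA against T-PFOS, and 12 to 40, 2 to 10 and 1340 to 1840 for the doses of L-PFOS, TCDD and PFUdA. Leaving out some single array ended 11 of 26 named calls for L-PFOS 10 uM and 10 of 43 for L-PFOS 40 uM. It ended 5 of 35 for T-PFOS, 3 of 23 for TCDD 0.03 nM and 10 of 32 for TCDD 1 nM. For PFUdA it ended 14 of 41 at 1 uM and 10 of 70 at 10 uM. Against L-PFOS it ended 3 of 8 for T-PFOS and 9 of 63 for PFUdA, and against T-PFOS 11 of 60 for PFUdA. For the doses of L-PFOS, TCDD and PFUdA it ended 8 of 12, 0 of 1 and 17 of 60.

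The labels give no meaning to shared replicate numbers. With the replicate block 69 probes passed for the L-PFOS doses and 12 for the TCDD doses, and no other count moved by over 1.5 times. Arrays of the same number correlated from -0.569 to 0.783 in their residuals (mean 0.069), and 10 of 38 correlated best with their own number, where chance would give 7.6. On different slides the mean for arrays of the same number was 0.007 (106 pairs). For the L-PFOS doses, 4 of the 5 pairs of the same number lay over 0.1 (mean 0.239, -0.482 to 0.756). A hint of pairs is not excluded there, although both arrays of replicate 5 lie on the same slide. For the TCDD doses 1 of 4 pairs lay over 0.1 (mean 0.004).

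Of the 56 list results, 12 passed with an estimated correlation. With median centring 35 passed, 31 of them shared, with slide as a block 50 (43), without background correction 53 (51) and without the 8 arrays 59 (50). Shared probes that passed numbered 137 for L-PFOS and T-PFOS at 10 uM, 134 for the L-PFOS doses, 188 for the TCDD doses, 304 for the PFUdA doses, 288 for T-PFOS and 121 for L-PFOS with PFUdA at 10 uM. With the DMSO arrays split these counts were 34, 35.5, 73.5, 122, 101.5 and 32.5. At an unadjusted p, on all DMSO arrays, they were 1485, 1466, 1065, 1498, 1721 and 1150.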

Other observations

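None of the tests in this part was chosen after the result was seen. Genes of p53 and apoptosis did not pass as a list at 10 uM PFUdA (mean 0.24, adjusted p = 0.0718), although 4 of 17 rose and 1 fell, also adjusted over the list alone. GADD45G, a stress-induced growth arrest gene, rose by 0.83 (SE 0.105, adjusted p = 7.8e-07), and CDKN1A by 0.60 (SE 0.142, adjusted p = 0.00493). The heat shock genes HSPA2 and HSPA9 rose by 0.68 (SE 0.118) and 0.39 (SE 0.094). The protease gene FAP, a fibroblast marker, rose by 1.11 (SE 0.19). Over all 13 comparisons the lists of endothelial, heat shock and macrophage genes never passed, with an adjusted p of 0.114 to 0.996, 0.0683 to 0.978 and 0.228 to 0.978.

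Among the 72 pairs of arrays of the same group, the correlation of ratios ran from -0.24 to 0.75, with a median of 0.348. The correlation between replicates was thus low for many pairs. It is taken over probes as a whole, so it does not measure agreement for the genes that changed. No pair shared more than 0.0152% of its raw Cy5 values, and pairs across groups were not checked for this.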
